A study of Mus musculus with 6 samples.

How the data were processed

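RNA was sequenced from mouse hippocampus in 6 libraries, 3 labelled shControl and 3 labelled shHepaCAM. Groups and replicate numbers were taken from the library titles. The deposited values are RPKM, one file per library, computed by the authors. Per the submitters' processing notes, TopHat2 2.0.12 and Bowtie2 2.0.6 were used with build mm39; the read counter, the annotation and the strand setting are not given in the sources used here. The annotation used here was GENCODE M21, which is on another build, so it served for names, gene classes and exon lengths and no coordinate is given. Gene symbols were found for 29805 of the 29872 identifiers.

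Because RPKM values are whole multiples of what 1 read is worth for a gene and library, the depth behind each library and the reads of each gene were worked out from the deposited RPKM values. With the annotated exon lengths, 27390 genes (91.9% of the genes with such a length) came out whole within 0.01 read in every library. A step of their own gave whole reads for 2398 more, so that 99.7% of all genes were resolved and 84 were not. Depth was 17109777, 17341842 and 14903198 reads in shControl replicates 1, 2 and 3 and 15816576, 16136797 and 16384937 reads in shHepaCAM replicates 1, 2 and 3. On simulated values, 99.9% of genes resolved had the true reads. The closest pair of libraries differed by a chi-square of 4.04 per degree of freedom over their reads, above sampling noise, so no library was taken as a repeat of another. These reads served for the comparison of library pairs, floors, intervals, the RPM values of immunoglobulin genes, the read shares of variable segments, the simulated libraries and 1 added alternative. Intervals on reads are at the 95% level and floors at 3 reads. Both cover counting error only, and floors only that of the group with 0 reads.

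The main test was limma 3.58.1 with a mean-variance trend, in R 4.3.3, on log2(RPKM + 1) for the 13864 genes with a mean of at least 1 RPKM over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. The design was written for count or normalized files, and the normalized branch was used. Hepacam was also tested by an exact two-sided permutation test. Gene lists were tested with camera at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over 28 lists, and again with an estimated correlation and with fry. None of the 28 lists passed with an estimated correlation. The lists cover sterol and lipid genes, glial, neuronal, vascular, choroid plexus, blood and immune markers, neighbouring brain regions and stress and activity responses; 296 of their 325 genes were tested. Another 8 lists were written after the data were seen.

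The named genes are Hepacam; per direction the 8 largest log2 changes and the 4 smallest p-values among genes past the threshold whose groups do not overlap, leaving out predicted genes, clone names and pseudogenes; and for each list the members past the threshold, or the 4 with the smallest p where more or none passed, with any member of the cholesterol list. The test, the lists and this rule were fixed before the data were examined. Some genes that this rule takes are not reported here, though they count in the totals. Mylip and Hspa5 were named after their values were seen. On simulated libraries of 13840 genes with known changes between shHepaCAM and shControl, limma called 47.8% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, and 7.61% of its calls were unchanged genes. The simulated dispersion was 0.01, so these shares hold only for libraries with that spread.

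Alternatives were quantile normalization, scaling to the median gene, no filter, a filter at 5 RPKM, limma without trend, array weights, a pseudocount of 0.1, a replicate block, other thresholds, other list tests and leaving out each library. Those added after the data were seen were limma-voom on the whole reads, leaving out both libraries low in choroid plexus transcripts, log2 Ttr as a covariate, protein-coding genes only, no immunoglobulin or T cell receptor segments, and removal of a GC and length trend. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.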

Results

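Gene expression was measured by RNA sequencing of hippocampus from C57BL/6J mice. In the knockdown group (shHepaCAM, 3 libraries), an adeno-associated virus (AAV), a gene delivery vector, was given in the CA1 field on both sides of the brain, with a short hairpin RNA (shRNA) against Hepacam, which encodes the cell adhesion molecule hepaCAM of astrocytes. A control group (shControl) gave the other 3 libraries. The labels call the control genotype wild type and its libraries shControl, and do not say whether the control mice received a vector. The deposited values were RPKM, reads scaled by gene length and library depth, for 29872 genes in each library. Between 14903198 and 17341842 reads stood behind the normalization of the control libraries, and between 15816576 and 16384937 reads behind that of the knockdown libraries. The labels do not say that the libraries came from separate mice, so the p-values measure the spread between these libraries, which may be technical. The study asked how gene expression in the hippocampus differs after hepaCAM knockdown, and its title names the cholesterol synthesis pathway.

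Hepacam itself (ENSMUSG00000046240) was lower in all 3 knockdown libraries than in any control library. It stood at 37.3, 33.4 and 35.9 RPKM in shControl replicates 1, 2 and 3, and at 24.4, 22.6 and 20.9 RPKM in shHepaCAM replicates 1, 2 and 3. The group means were 35.6 ± 1.98 (SD, n = 3) and 22.6 ± 1.76 RPKM (SD, n = 3), so the transcript was 36.3% lower in whole hippocampus. In limma it fell by 0.63 on the log2(RPKM + 1) scale (SE 0.07, adjusted p = 0.00924). An exact two-sided permutation test gave p = 0.1, the smallest p that 3 libraries against 3 allow. Without shControl replicate 3 the change was -0.62 with an adjusted p of 0.0526 in limma, and adjusted p-values ranged from 0.00383 to 0.0695 over all alternatives.

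**Figure D1:**
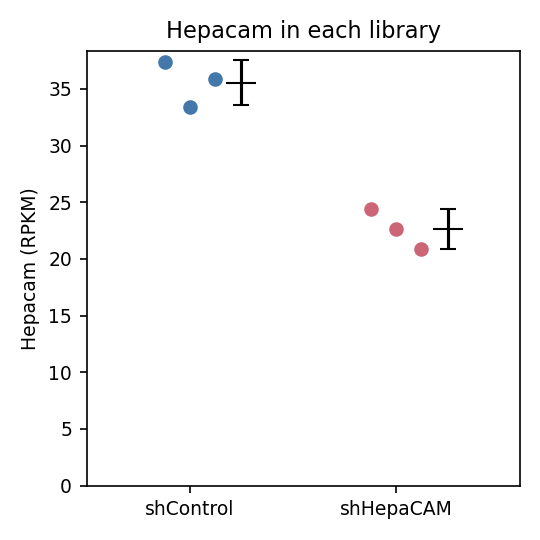
Hepacam level in RPKM in each of the 6 libraries (points, by group), with the group mean and SD (black). The 3 shHepaCAM libraries lie between 20.9 and 24.4 RPKM, below the 3 shControl libraries at 33.4 to 37.3 RPKM.

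Across the transcriptome, 842 of 13864 genes tested differed between the groups at an adjusted p of 0.05 in limma. Of these, 587 were higher and 255 lower in the knockdown libraries, and 389 also differed by at least 1.5-fold on the log2(RPKM + 1) scale. Protein-coding genes made up 745 of the 842. With single libraries left out, the count was 235, 126 and 98 without shControl replicates 1, 2 and 3, and 867, 421 and 328 without shHepaCAM replicates 1, 2 and 3. Of 70 genes called among those taken for naming, 31, 37 and 39 lost the call without shControl replicates 1, 2 and 3, and 9, 17 and 17 without shHepaCAM replicates 1, 2 and 3. The direction split depended on scaling: with each library scaled to its median gene, 336 genes were higher and 347 lower, and with quantile normalization 391 were higher and 341 lower.

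The largest rises were in antibody transcripts. Igkc, the constant region of the kappa light chain, averaged 3.44 ± 1.22 RPKM (SD, n = 3) in control and 1051 ± 632 RPKM (SD, n = 3) in knockdown libraries, a log2 change of 7.74 (SE 0.44, limma adjusted p = 0.000682). The heavy chain constant regions Ighg2c, Igha and Ighg2b rose by 7.18, 5.63 and 5.08, and Jchain, which joins antibody subunits, rose by 4.68. Ighg2c stood at 108, 79.3 and 690 RPKM in shHepaCAM replicates 1, 2 and 3, and its rise was 6.22 without shHepaCAM replicate 3 and 7.77 without shHepaCAM replicate 2; that of Jchain was 5.42 without shHepaCAM replicate 1. The variable segments Igkv4-53, Ighv2-9 and Igkv8-24 had 0 reads in all 3 control libraries and 4225, 938 and 399 reads over the knockdown libraries. Against a floor of 3 reads over the control group they were at least 1438-fold, 319-fold and 136-fold higher, a bound that covers counting error only. Igkv4-53 had 41, 3031 and 1153 reads in shHepaCAM replicates 1, 2 and 3, and its bound was 610-fold without shHepaCAM replicate 2; that of Ighv2-9 was then 208-fold. Without shControl replicates 1 and 2, each left out alone, the floor rests on less depth, and the bounds were 939-fold and 933-fold for Igkv4-53, 209-fold and 207-fold for Ighv2-9 and 88.7-fold and 88.1-fold for Igkv8-24. Variable segments share sequence with one another, so the assignment of reads to a single segment is uncertain. The smallest p-values among genes that rose belonged to Cd74, H2-Ab1, Ighg2b and Lag3. Cd74, the invariant chain of class II antigen presentation, went from 5.08 ± 0.58 to 50.2 ± 8.64 RPKM (SD, n = 3 each; log2 change 3.07, SE 0.13, limma adjusted p = 0.000246). Lag3, an inhibitory receptor that binds class II molecules, went from 8.24 ± 0.84 to 26.7 ± 1.67 RPKM (SD, n = 3 each). Igkv4-53 and Ighv2-9 lost the call in 11 and 9 of 18 alternatives, with adjusted p-values up to 0.548 and 0.254. Among these were leaving out any 1 library other than shHepaCAM replicate 1, with adjusted p-values of 0.0829 to 0.125 for Igkv4-53 and 0.0604 to 0.095 for Ighv2-9. Ighg2c and Jchain were not called when limma-voom was run on the whole reads worked out from the values, and Jchain was not called without both shControl replicate 1 and shHepaCAM replicate 3 (adjusted p = 0.0573).

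**Figure D2:**
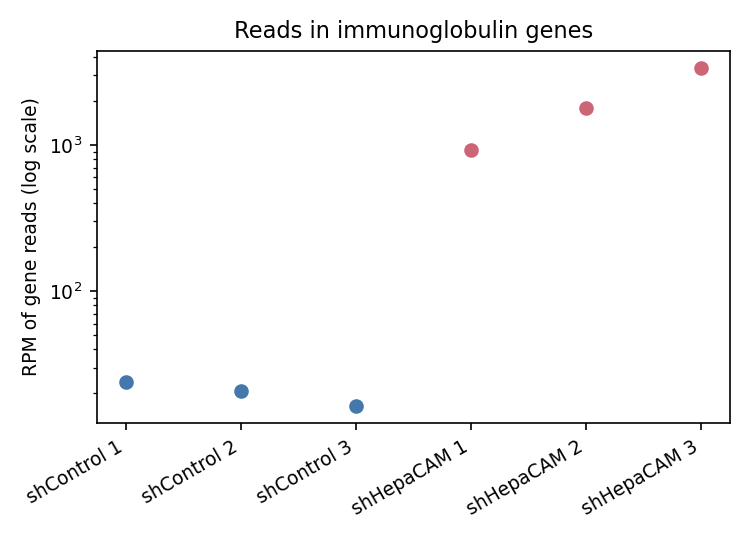
Reads in the 170 immunoglobulin genes in each library, scaled to the depth over genes (RPM), on a log axis (blue, shControl; red, shHepaCAM). The control libraries lie between 16.4 and 23.7 and the knockdown libraries at 917, 1779 and 3376 RPM.

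Among genes that fell, the largest changes outside microRNA genes were in sterol synthesis. Among these, Msmo1, Hmgcs1 and Fdft1, all enzymes of cholesterol synthesis, and Stard4, a sterol carrier protein, fell by 1.38, 1.24, 1.13 and 1.13. The microRNA genes Mir6941, Mir3072 and Mir6362 also passed the test but rest on few reads and overlap longer genes, Jag2, Mirg and Dgkg, from which their reads cannot be told apart. Mir6941 had 12 reads over the control and 1 over the knockdown libraries, a ratio of 0.085 with a counting interval of 0.00199 to 0.575, and lost the call with any 1 library other than shHepaCAM replicate 2 left out (adjusted p of 0.0599 to 0.124). Mir3072 had 9 and 0 reads and was 2.94-fold lower against a floor of 3 reads. Without shHepaCAM replicates 2 and 3, each left out alone, this was 1.96-fold and 1.94-fold. The floor leaves out the counting error of the 9 reads, and the counting interval of the ratio reached 0.517. Mir6362 had 35 and 8 reads, with a limma adjusted p of 0.0558 without shHepaCAM replicate 2. Smoc2, Enc1 and Pip4k2b had the smallest p-values after Mir3072. Enc1, which encodes an actin-binding protein of neurons, went from 239 ± 7.41 to 145 ± 8.42 RPKM (SD, n = 3 each; log2 change -0.72, SE 0.07, limma adjusted p = 0.00501). Smoc2, an extracellular calcium-binding protein, went from 11.8 ± 0.09 to 5.75 ± 0.54 RPKM (SD, n = 3 each).

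Enzymes of cholesterol synthesis were lower as a group. Of 19 enzymes tested, 12 fell, 0 rose and 7 did not pass the threshold over all genes. Adjusted over the list alone, 17 fell. The median log2 change was -0.71. Hmgcs1, an enzyme early in the pathway, went from 37.6 ± 0.86 to 15.6 ± 3.12 RPKM (SD, n = 3 each; log2 change -1.24, SE 0.13, limma adjusted p = 0.0052). Mvk, Mvd, Sc5d, Hsd17b7, Idi1, Fdft1, Sqle, Acat2, Msmo1 and Cyp51 also fell. Ebp changed by 0.02 with an adjusted p of 0.866. Fdps lay under the filter, at 0.20 ± 0.08 and 0.13 ± 0.05 RPKM (SD, n = 3 each); the treatment of reads that fit several places is not given in the sources used here, so these values may understate its level. The list ranked lower than other genes in camera (adjusted p = 2.1e-18), but not with an estimated correlation between its genes (adjusted p = 0.255). Fry, which tests a list against no change and not against other genes, gave it an adjusted p of 0.00634. Because the study's title names this pathway from these libraries, the list is not independent evidence of its direction. The number of enzymes called was 16 with quantile normalization and 16 with scaling to the median gene. It was 7, 6 and 5 without shControl replicates 1, 2 and 3. It was 4 without both shControl replicate 1 and shHepaCAM replicate 3, which were low in choroid plexus transcripts. This last alternative was chosen after the data were seen.

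**Figure D3:**
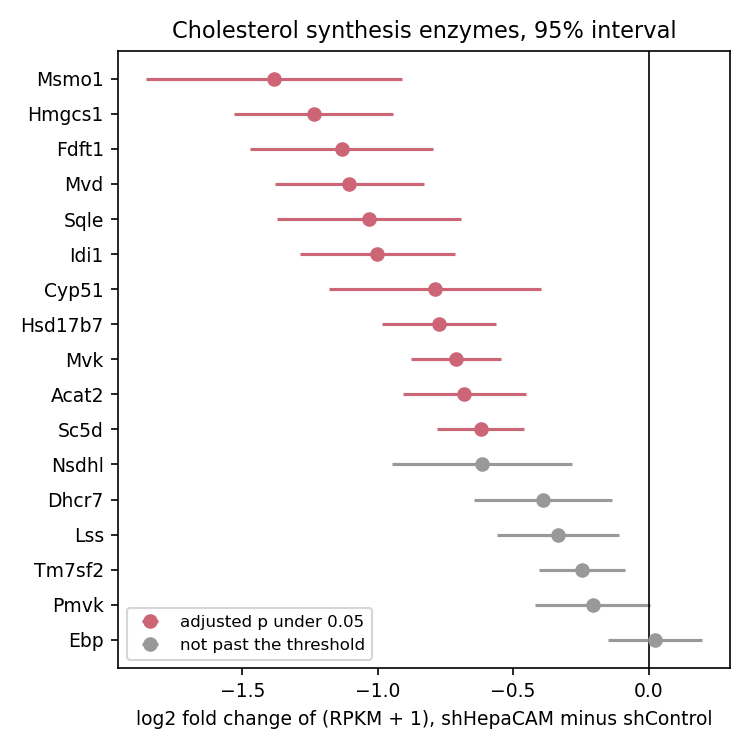
Log2 fold change of RPKM + 1 (shHepaCAM minus shControl, 3 libraries each) for 17 of the 19 cholesterol synthesis enzymes tested, with 95% intervals from limma. Red marks the 11 enzymes drawn that are past the adjusted threshold, which lie between -1.38 and -0.62.

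Genes around sterol balance moved in both directions. In the list of sterol regulation and uptake, 4 of 13 genes fell and 0 rose, among them Stard4, the sterol-sensing regulator Insig1 and the transcription factor Srebf2, by 1.13, 0.97 and 0.48. Adjusted over the list alone, 4 fell. The list had a median of 0.04 and a mean of -0.22, and camera gave an adjusted p of 0.133. Of 14 genes of sterol efflux, carriers and turnover, 5 rose and 0 fell, and 6 rose adjusted over the list alone. The cholesterol exporters Abca1 and Abcg1 rose by 1.06 and 0.38, the lipid carriers Apoe and Apod by 0.68 and 0.78, and Mylip, a ubiquitin ligase, by 0.54. Apoe went from 1315 ± 26.6 to 2117 ± 182 RPKM (SD, n = 3 each). Camera gave this list an adjusted p of 0.0492, and of 0.281 with an estimated correlation. In camera it was 0.0637, 0.0647 and 0.154 without shControl replicate 1, shControl replicate 3 and shHepaCAM replicate 1. The list also missed the threshold with a pseudocount of 0.1 and with the replicate block. The same held without both libraries low in choroid plexus transcripts and with the GC and length trend removed. These further camera values were 0.0525 to 0.0632. Fry, which tests a list against no change and not against other genes, gave this list an adjusted p of 0.00372. Of 12 genes of fatty acid synthesis, 4 fell and 0 rose: Acsl3, Fads2, Acss2 and Acly, by 0.61, 0.67, 0.39 and 0.33. In this order they lost the call in 1 of 20, 6 of 20, 9 of 19 and 12 of 20 alternatives. The number of genes called lower ran from 0 to 8. Adjusted over the list alone, 9 fell and 1 rose. The list ranked lower in camera (adjusted p = 6.6e-07; adjusted p = 0.255 with an estimated correlation).

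Immune and microglial genes were higher. All 10 genes of antigen presentation rose, over all genes and adjusted over the list alone, with a median log2 change of 1.31. H2-Ab1, a class II chain, went from 3.56 ± 0.50 to 24.2 ± 2.41 RPKM, and B2m, the class I light chain, from 220 ± 18.6 to 431 ± 12.5 RPKM (SD, n = 3 each). H2-D1 rose by 1.33, and genes of the H2 family share reads. Camera gave the list an adjusted p of 1.4e-13 (adjusted p = 0.159 with an estimated correlation). Of 14 microglia markers, 9 rose and 0 fell, and 11 rose adjusted over the list alone, with a median of 0.67. The protease Ctss, the complement subunits C1qc and C1qb and the lipid receptor Trem2 rose by 1.01, 0.92, 0.95 and 0.94. Camera gave an adjusted p of 1.4e-09 (adjusted p = 0.255 with an estimated correlation). Of 14 interferon response genes, 4 rose and 0 fell, and 10 rose adjusted over the list alone. Rsad2, Gbp3, Rtp4 and Usp18 rose by 0.83, 0.61, 0.56 and 0.87 (camera adjusted p = 8.9e-05; adjusted p = 0.475 with an estimated correlation and 0.0898 in fry). With each library scaled to its median gene, Gbp3, Rtp4 and Usp18 no longer passed. Only 3 of the T and B lymphocyte markers were tested, of which Trbc2 and Trac, constant regions of the T cell receptor, rose by 0.96 and 1.10, and 3 rose adjusted over the list alone (camera adjusted p = 0.002; adjusted p = 0.255 with an estimated correlation). The 3 blood genes tested did not pass and had a median of -0.78 (camera adjusted p = 0.0187; adjusted p = 0.308 with an estimated correlation and 0.126 in fry); 2 of them fell adjusted over the list alone. Camera gave the blood list an adjusted p of 0.0633 with each library scaled to its median gene, 0.0609 with quantile normalization and 0.0527 with the GC and length trend removed.

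Astrocyte markers did not move as a group. Of 12 tested, Slc1a2, the main glutamate transporter of astrocytes, fell by 0.37 and 0 rose, while adjusted over the list alone 1 rose and 1 fell. The list's median was 0.08 and its mean 0.03, camera placed it lower with an adjusted p of 0.694, and the median turned to -0.01 with each library scaled to its median gene. Of 15 reactive astrocyte genes, 5 rose and 0 fell, and 9 rose adjusted over the list alone. Serpina3n, a protease inhibitor, and Vim, an intermediate filament, rose by 0.70 and 0.51, the chemokine Cxcl10 by 1.07 and the complement inhibitor Serping1 by 0.87. Camera gave an adjusted p of 2.6e-05 (adjusted p = 0.308 with an estimated correlation). With each library scaled to its median gene, Vim no longer passed. None of 9 hepaCAM partners and astrocyte channels passed in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.177, and 0.0404 in fry, which tests against no change, lower). Mlc1, which binds hepaCAM, was at 69.3 ± 1.94 and 61.3 ± 5.04 RPKM (SD, n = 3 each; log2 change -0.18, adjusted p = 0.182).

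In neuronal lists few genes passed. Of 18 synaptic and plasticity genes, Camk2a and Snap25 fell by 0.34 and 0.70 and Bdnf rose by 0.77, with the same counts adjusted over the list alone (median -0.01, camera adjusted p = 0.371). With each library scaled to its median gene Snap25 no longer passed. Of 12 immediate early genes, which respond to neuronal activity, Btg2, Npas4 and Ier2 rose by 1.58, 1.48 and 1.40 and 0 fell, and 8 rose adjusted over the list alone. Npas4 stood at 17.3, 31.7 and 15.4 RPKM in shHepaCAM replicates 1, 2 and 3. Camera gave an adjusted p of 0.000206 (adjusted p = 0.528 with an estimated correlation and 0.126 in fry). Of 11 genes of the unfolded protein response, Ddit3, Chac1 and Atf3 rose by 0.98, 1.05 and 1.90 and 0 fell, also adjusted over the list alone; these are targets of stress-induced transcription factors, and the chaperone Hspa5 was at -0.10 (camera adjusted p = 0.0583). That list ranked higher with an adjusted p of 0.0205 with quantile normalization, 0.0055 with no filter, 0.0471 with array weights, 0.0222, 0.0464 and 0.0202 without shControl replicate 2, shControl replicate 3 and shHepaCAM replicate 2. Fry, which tests a list against no change and not against other genes, gave it an adjusted p of 0.00676. Trpc6 rose by 0.73 among 9 dentate granule neuron markers, where 1 rose and 1 fell adjusted over the list alone. That list had a median of -0.02, a mean of 0.02 and a camera adjusted p of 0.639. Penk rose by 1.21 among 6 striatum markers, of which 2 rose adjusted over the list alone (camera adjusted p = 0.639). No CA1 marker of 8 passed (median 0.13, camera adjusted p = 0.639) and no CA2 and CA3 marker of 8 (median -0.23, camera adjusted p = 0.055), although 2 of the latter fell adjusted over the list alone. The CA2 and CA3 list ranked lower with an adjusted p of 0.0414, 0.0281 and 0.0123 without shControl replicate 2, shHepaCAM replicate 1 and shHepaCAM replicate 3, 0.0446 with limma-voom, 0.0159 without both libraries low in choroid plexus transcripts and 0.0421 with log2 Ttr as a covariate.

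The remaining lists had 0 genes past the threshold in limma, over all genes and adjusted over the list alone. Interneuron markers had a median of -0.02 and a mean of 0.01 (camera adjusted p = 0.694), and thalamus and habenula markers a median of 0.04 (camera adjusted p = 0.975, placed lower). Oligodendrocyte and myelin genes had a median of 0.17 (camera adjusted p = 0.429), oligodendrocyte precursor markers 0.08 (0.383), endothelial and pericyte markers -0.02 (0.429) and fibroblast and meningeal markers 0.28 (0.619). Without shHepaCAM replicate 3, the oligodendrocyte and the fibroblast lists ranked higher (adjusted p = 0.00687 and 0.0287), the former also without both libraries low in choroid plexus transcripts (0.0104), and without shHepaCAM replicate 2 the endothelial list ranked lower (0.0298). Neocortex markers had a median of -0.18, with a camera adjusted p of 0.0334 that was 0.0629 with each library scaled to its median gene, 0.0588 with the GC and length trend removed, 0.0654 without shControl replicate 3 and 0.102 without shHepaCAM replicate 2 (adjusted p = 0.281 with an estimated correlation and 0.126 in fry). The 13 mitochondrially encoded genes had a median of -0.21 (camera adjusted p = 0.000176; adjusted p = 0.475 with an estimated correlation and 0.2 in fry).

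**Figure D4:**
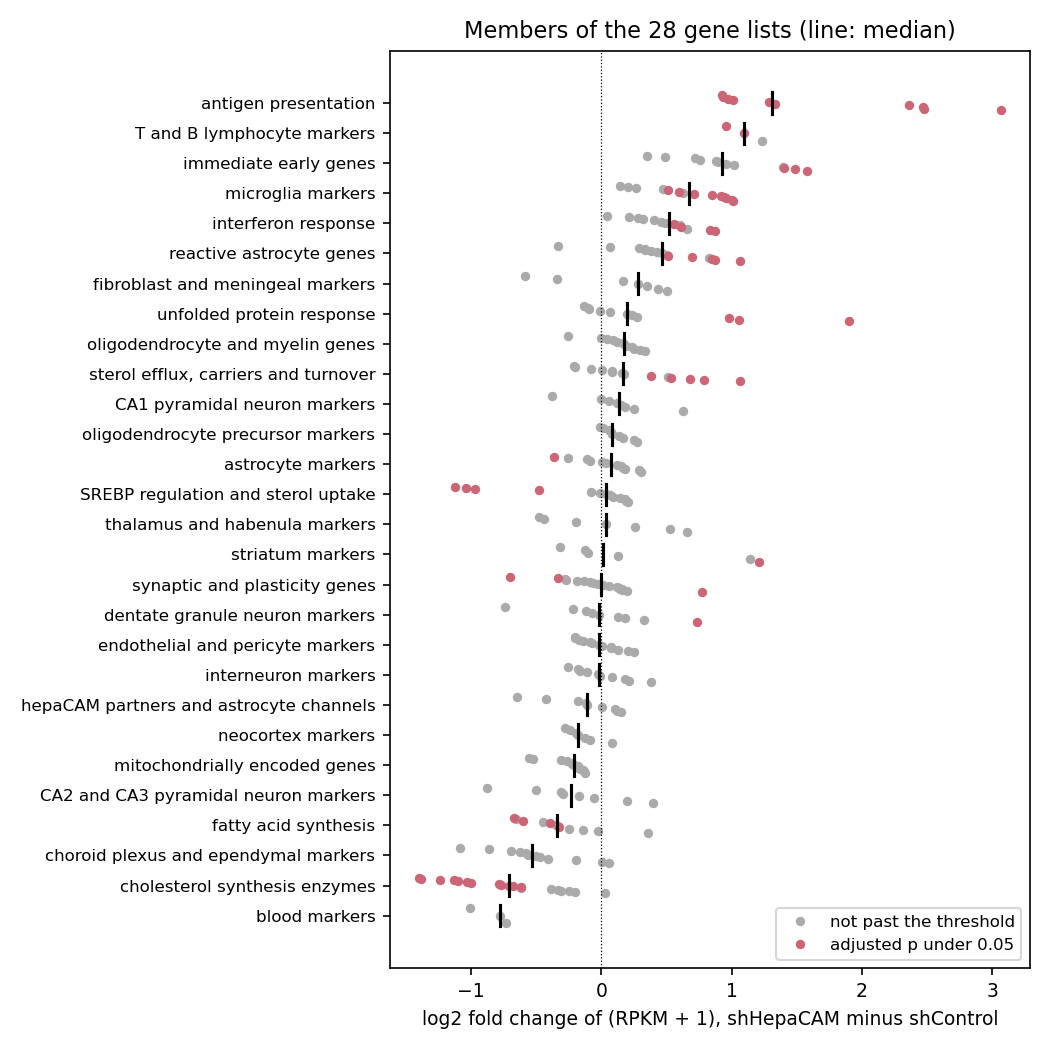
Log2 fold change of RPKM + 1 (shHepaCAM minus shControl, 3 libraries each) for every tested member of the 28 gene lists, with a line at each list's median. Red marks genes past the adjusted threshold; all 10 antigen presentation genes and 12 of 19 cholesterol synthesis enzymes are red, on opposite sides of 0.

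Choroid plexus transcripts split the libraries across the groups. Ttr, the most abundant of them, stood at 62.1, 4192 and 3617 RPKM in shControl replicates 1, 2 and 3 and at 2278, 1660 and 25.5 RPKM in shHepaCAM replicates 1, 2 and 3. Of the 11 other choroid plexus and ependymal markers, 10 had both their lowest values in shControl replicate 1 and shHepaCAM replicate 3. None of the 12 markers passed between the groups in limma, over all genes or adjusted over the list alone (median -0.53, camera adjusted p = 0.136), but the list ranked lower in the knockdown libraries under 4 alternatives: without shControl replicate 1 (median -1.51, adjusted p = 6.1e-05), without shHepaCAM replicate 1 (median -0.97, adjusted p = 0.0467), with array weights (median -0.84, adjusted p = 0.0468) and without both low libraries (median -0.76, adjusted p = 7.8e-08). Whether choroid plexus transcripts differ between the groups is therefore open. Without those 2 libraries, an alternative chosen after the data were seen, 104 genes passed, of which 91 were higher and 13 lower.

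**Figure D5:**
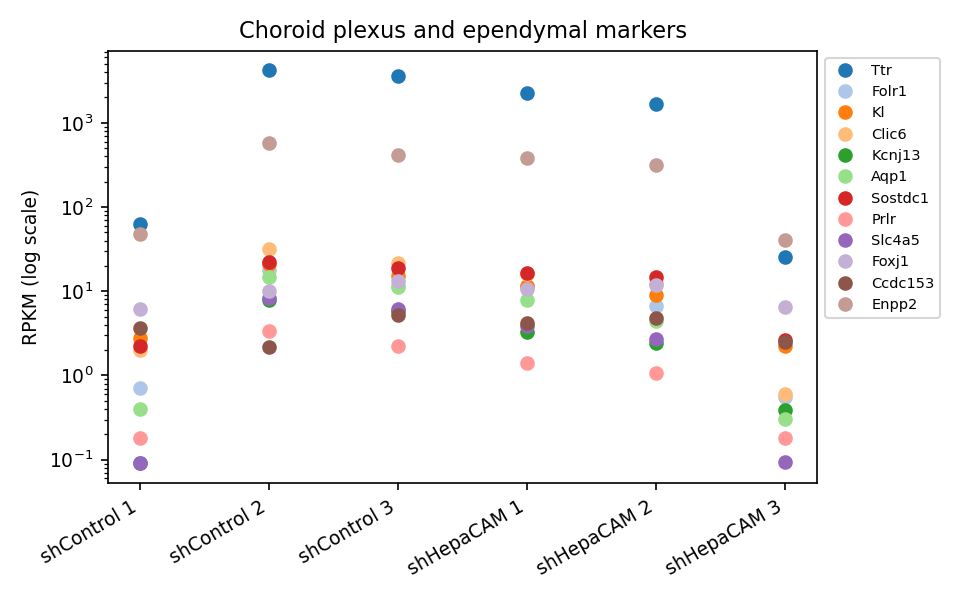
RPKM of 12 choroid plexus and ependymal markers in each library, on a log axis, one colour per gene. For Ttr, shControl 1 and shHepaCAM 3 lie at 62.1 and 25.5 RPKM and the other 4 libraries between 1660 and 4192 RPKM.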

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

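The alternatives added after the data were seen are limma-voom, both libraries low in choroid plexus transcripts left out, the Ttr covariate, the gene subsets and the GC and length trend. Hepacam stayed lower under all 20 alternatives (-0.72 to -0.54, and -0.68 to -0.58 when 1 library was left out), past the threshold in 18; the exceptions were -0.62 without shControl replicate 3 and -0.54 without both low-choroid libraries. The cholesterol list's median stayed between -0.82 and -0.59 under 22 alternatives and its camera call was lost only with an estimated correlation (median -0.71, adjusted p = 0.255). With an estimated correlation 0 of the 27 other lists passed, against 11 with the preset one, 8 with fry and 8 to 14 over the alternatives other than the estimated correlation. No pairing by replicate number was seen: the correlations of same-numbered deviations were -0.21, 0.02 and -0.14. The highest value, 0.27, joined shControl replicate 1 with shHepaCAM replicate 3, the libraries low in choroid plexus transcripts. That difference may hide a weaker pairing, so a pairing by number is not excluded. With the replicate block, which leaves fewer residual degrees of freedom, 157 genes passed, 112 higher and 45 lower. Leaving out 1 library, which leaves fewer samples, gave 98 to 867 genes, 75 to 551 higher and 23 to 316 lower, and 5 to 12 cholesterol enzymes lower. Without both low-choroid libraries 104 passed, 91 higher and 13 lower, with 4 cholesterol enzymes. With no filter, where more genes are tested, 169 passed, 121 higher and 48 lower, with 7 cholesterol enzymes. Genes higher numbered 391 with quantile normalization, 336 with scaling to the median gene and 372 with the GC and length trend removed. The median log2 change of all genes was 0.05 in the main fit and -0.02, -0.03 and -0.01 under these settings. The excess of rises was smaller or absent where this offset was not above 0, and the source of the offset was not tested. Genes lower numbered 153 in limma without trend, and the cause of that was not tested. By threshold, 389 genes passed with a 1.5-fold change as well (310 higher, 79 lower), 1677 at an adjusted p of 0.1 (1157 and 520) and 3356 at an unadjusted p of 0.05 (2258 and 1098). The mitochondrially encoded list turned to a median of 0 with quantile normalization, which sets the highest ranks of all libraries equal. Of 70 named genes called, no direction turned under any alternative; 43 lost the call without both low-choroid libraries, 39 without shControl replicate 3 and 27 with the replicate block.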

Other observations

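All tests in this part were chosen after the data were seen, and the 8 gene lists below were written then, so their directions are not independent of these libraries. Of 18 genes of disease-associated microglia, a state of microglia described around damage, 9 rose and 1 fell; Cst7 went from 7.45 ± 2.46 to 32.3 ± 9.23 RPKM and Itgax from 0.998 ± 0.14 to 5.25 ± 1.09 RPKM (SD, n = 3 each), while Fth1 fell by 0.53. Of 9 complement genes 6 rose, among them C3 by 2.25 and C4b by 1.21. The rest of those that rose, C1qa, C1qb, C1qc and Serping1, are also in the microglia or reactive astrocyte lists above. Trem2 and Tyrobp, which rose among the genes of disease-associated microglia, are also microglia markers. Of 6 B lineage and plasma cell genes 2 rose, Jchain and Mzb1. Of 14 p53 targets 5 rose, among them Cdkn1a, a cell cycle inhibitor, by 1.22 and Phlda3 by 0.72. Camera gave these lists adjusted p-values of 2.1e-06, 1.5e-07, 0.000336 and 0.00213, and an adjusted p of 0.137 each with an estimated correlation.

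Of 14 pan-neuronal genes 4 fell and 0 rose, among them Hpca, a calcium sensor of hippocampal neurons that went from 749 ± 24.8 to 377 ± 43.3 RPKM (SD, n = 3 each), and Slc17a7 and Tubb3, which fell by 0.64 and 0.48 (camera adjusted p = 2.1e-06; adjusted p = 0.137 with an estimated correlation). Of 13 snoRNA host RNAs 4 rose, among them Snhg5 and Zfas1 by 0.97 and 0.81. Of 14 integrated stress response genes 4 rose and 1 fell, with Shmt2 at 0.51 and Asns at -0.28. Ddit3 and Chac1, which were among those that rose, are also in the unfolded protein response list above. The snoRNA host and integrated stress response lists each had a camera adjusted p of 0.0009 and an adjusted p of 0.137 with an estimated correlation. Of 4 monocyte and granulocyte markers 1 rose, Ly6c2 (camera adjusted p = 0.428; adjusted p = 0.466 with an estimated correlation and 0.0178 in fry, which tests against no change).

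The real grouping called 842 genes and the highest of the other splits called 1. Every other split mixes libraries of both groups on each side, so a difference between the groups widens its spread and lowers its count. The contrast of 842 with 1 therefore overstates how far the real grouping stands apart. Of the 10 splits of the 6 libraries into groups of 3, only the real one, 1 of 10, gave as many genes, and 10 splits are too few for a share under 0.05.

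Immunoglobulin genes stood at 20.3 ± 3.70 RPM (SD, n = 3) in control libraries and at 917, 1779 and 3376 RPM in shHepaCAM replicates 1, 2 and 3. Blood left in the tissue would raise hemoglobin as well, but the highest upper 95% bound of the 3 blood genes tested was 0.0186, against a median rise of 3.08 for the immunoglobulin genes called. Material from 1 source in all 3 libraries would give them like variable segments, but the highest correlation of segment read shares between knockdown libraries, across genes, was 0.087. Igkv4-74, Igkv4-53 and Igkv19-93 led in shHepaCAM replicates 1, 2 and 3 with 32.6%, 35.7% and 67.9% of segment reads. Igkv4-53 also had 6.65% of segment reads in shHepaCAM replicate 3, and a correlation led by a few segments does not show such sharing. These values argue against 1 source for most segment reads, and a smaller shared part is not excluded. A hypothesis is that B lineage cells, each library with a few dominant clones, may be present in the knockdown tissue; of 5 B lineage genes other than Jchain, 1 passed and rose, which is too few to decide. Whether the vector, the hairpin or the loss of Hepacam would bring them stays open, since the design does not separate these.

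The fall of cholesterol synthesis enzymes, with a median of -0.71, was set against changes in tissue makeup. Added immune cells would dilute resident cells alike, but the lower quartile of 81 resident cell markers was -0.11; fewer astrocytes would lower their markers as much, but the lowest astrocyte marker was at -0.37. Unequal choroid plexus would take the fall away once Ttr is a covariate, but the median was then -0.71; with both low-choroid libraries left out it was -0.59, with 4 enzymes past the threshold, but choroid plexus transcripts were still lower in the knockdown libraries then, so that leave-out does not balance them. A hypothesis is that cells may sense more sterol, which would lower targets of SREBP2 and raise those of the LXR receptors; of 10 LXR targets, 4 passed and rose (Abca1, Abcg1, Mylip and Apoe) and 6 did not pass, with Scd1 at -0.66, so this stays open. Apoe and Abca1 are also expressed by microglia, whose markers rose, and the tables do not separate that from a response to sterol.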
